A study of Homo sapiens with 9 samples.

How the data were processed

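LNCaP is a human prostate cancer cell line. Polyadenylated RNA of LNCaP cells was sequenced in 9 libraries, 3 biological replicates in each of 3 groups, which are vehicle (DMSO), 1 nM R1881, and 1 nM R1881 with 10 µM MEL-6. Groups and replicate numbers were taken from the sample titles, and the columns of the deposited table were matched to samples by the library names and worksheet cells in the sample descriptions. Per the labels, RNA was isolated with a column kit and libraries were made with the TruSeq RNA kit of Illumina, and neither the labels nor the table say whether strand was kept or used.

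The deposited table holds 1 value per gene and library, with gene symbols and coordinates on GRCh37 (hg19), the build named with CASAVA 1.8 in the submitters' processing notes. Its sheet is named for counts, but the authors' values were RPKM, reads per kilobase of gene model scaled to library size. The values had 5 decimals, summed to between 350381 and 365815 per library, and in low genes were multiples of a step that scaled inversely with exon length and differed between libraries by a single factor. The authors' annotation, read filters and total read numbers were not stated. The table also held the authors' own comparison columns, which were differences of means, a pooled SD, significance marks and directions, whose test was not stated. They were used only as values beside the calls made here. The table had 25142 entries, of which 5883 were at 0 in every library and none was mitochondrial. Another 17 carried names that a spreadsheet had turned into dates and could not be named. For the 20 symbols placed on both X and Y, the Y entries were at 0 and the X entries were used.

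Depth was estimated from the steps of the low values. In 1060 low genes, 52.8% had values that were whole multiples of the step of 1 read in all libraries within a relative tolerance of 0.0005, against 0.0943% with permuted depths. Steps were turned into reads with exon-union lengths from the GENCODE annotation supplied with the data, which is on a newer build and was used for lengths only, matched by symbol for 83.1% of the entries, and since the authors' gene models may differ in length, the totals are estimates. In M (mega) reads they were 11.0, 7.17 and 9.0 for vehicle replicates 1 to 3, 13.6, 13.0 and 18.6 for R1881, and 6.62, 11.9 and 10.4 for R1881 with MEL-6. At these depths 3 reads in a 2 kb gene corresponded to between 0.0808 and 0.227 RPKM. Read-level counting error is known only through these estimates, so the error of every value was taken from the spread between replicates.

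The plan had been written for counts, with a count test, a count-based filter and a CPM floor for named genes. As the values were RPKM, the planned fallback was used, limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 0.5). Genes with at least 0.5 RPKM in at least 3 libraries were tested, 13295 in all. The pseudocount and this filter were chosen after the unit was known. No further scaling was applied, since RPKM already divides by library size. All 9 libraries were fitted in one model of group means with empirical Bayes moderation and an intensity trend (residual df 6, prior df 4.31), and p-values were adjusted by the Benjamini-Hochberg method over the tested genes in each comparison, with calls at an adjusted p under 0.05. All tests were two-sided. A log2 change is on the log2(RPKM + 0.5) scale, which understates the change of low genes. Levels are given as mean RPKM ± SD over 3 libraries and log2 changes as estimate ± SE. The comparisons were R1881 against vehicle, R1881 with MEL-6 against R1881, and R1881 with MEL-6 against vehicle.

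The comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 12 largest changes in each direction among called genes with at least 5 RPKM in the higher group (in place of a floor of 5 CPM) and groups that did not overlap. To these it added up to 4 called members of each list in each of the comparisons with R1881 against vehicle and MEL-6 against R1881, the 8 genes per direction that moved furthest beyond both other groups with MEL-6, and a small fixed set of genes that included the androgen-responsive KLK3, KLK2, TMPRSS2 and FKBP5. Of the genes this gave, 169 are in the tables, and the text names part of them. Other list members are named where they went against their list or where a count was small, and these were picked after their values were seen.

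Gene lists were tested with limma's camera on the same log2 values (in place of log2 CPM) with a preset inter-gene correlation of 0.01, and adjusted over 75 tests. These were the tests, in 3 comparisons, of every planned list with at least 3 tested members, and some of these lists and some planned genes are not reported here. Camera compares a list with all other tested genes. The lists reported were cholesterol synthesis and uptake, fatty acid synthesis, G2/M and mitosis, DNA replication and G1/S, ATF4 and amino acid stress, endoplasmic reticulum (ER) chaperones, cytosolic heat shock, NRF2 and oxidative stress, aryl hydrocarbon receptor targets, p53 targets, steroid metabolism, glucocorticoid-responsive genes, polyamine synthesis, glycolysis, hypoxia response, interferon-stimulated genes, secretory trafficking, luminal, basal, neuroendocrine, fibroblast and leukocyte markers, replication-dependent histones, ribosomal proteins and oxidative phosphorylation. Basal (2 tested members) and leukocyte markers (1) were too few for camera and are not among the 75 tests. Symbols were matched with older and newer names. Lists share members, for example 3 of the 17 tested NRF2 genes were also in another list.

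The share of the R1881 response left with MEL-6 was the log2 change of R1881 with MEL-6 against vehicle divided by that of R1881 against vehicle, in percent. Comparisons that share libraries were set beside 100 simulations of unchanged groups with the same shared libraries and beside the overlap of independent lists of the same sizes.

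Tests were checked on simulated data with known changes, drawn on the scale of these libraries with 67, 67 and 66 of 13295 genes changed by log2 0.5, 1 and 2. For R1881 against vehicle 64.2%, 89.6% and 100% of them were recovered. For MEL-6 against R1881 these shares were 55.2%, 86.6% and 100%, and for MEL-6 against vehicle 62.7%, 97.0% and 100%. Of unchanged genes 0.0687%, 0.0687% and 0.0840% were called in these comparisons. Camera called the raised list and 0 of the lists that shared no member with it in each. Genes were simulated independently of each other, so this does not show how often camera calls unchanged lists of correlated genes.

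Alternatives were median-of-ratios and upper-quartile scaling, no filter, a stricter filter of 1 RPKM, limma-voom on reads estimated from RPKM (12056 genes with an exon length), a fit on the compared groups alone, a replicate block, an estimated camera correlation, and leaving out each library in turn. Pseudocounts of 0.1 and 1 and leaving out features of 500 bp or less were added after the data were seen. Values were processed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9.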

Results

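Gene expression was measured in LNCaP cells, a human prostate cancer line from a lymph node metastasis that responds to androgen. Cells plated at 1 M per well (M, mega) were kept for 24 h in 5% charcoal-stripped serum, which removes steroids, and then treated for 18 h with DMSO (vehicle), with 1 nM of the synthetic androgen R1881, or with 1 nM R1881 and 10 µM of MEL-6, a compound known here by its code name. The experiment asked how MEL-6 changes expression in cells under androgen. Each group had 3 biological replicates, 9 libraries in all, with estimated depths from 6.62 to 18.6 M reads and between 15914 and 16822 genes above 0. The R1881 libraries were deeper, with a mean depth of 1.37 ± 0.279 relative to vehicle replicate 1, against 0.823 ± 0.175 for vehicle and 0.876 ± 0.248 for R1881 with MEL-6 (SD, n = 3). Replicates correlated at r = 0.994 to 0.997 on the log2 scale across genes, which are not independent of each other. In genes with moderate estimated reads, the median squared difference between replicates was 0.565 to 1.33 times the estimated counting variance. Counting error alone would give 0.455. The p-values below rest on this small spread, and whether it covers the variation between separate experiments cannot be told. The first principal component held 52.8% of the variance and set the R1881 libraries (scores 37.0 to 38.2) apart from vehicle (-16.8 to -14.0) and R1881 with MEL-6 (-24.2 to -21.0). The second held 24.3% and set vehicle (22.9 to 24.2) apart from R1881 with MEL-6 (-23.7 to -18.9). On the third, 6.87%, MEL-6 replicate 1, the shallowest library, lay at -19.6 against 6.27 and 16.1 for the other MEL-6 libraries.

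The first comparison, R1881 against vehicle, measured the response to androgen that MEL-6 was set against. R1881 raised the kallikreins and other classical androgen-responsive genes. KLK3 (chromosome 19, 51358171 to 51364020) encodes prostate-specific antigen and went from 308 ± 32.9 RPKM in vehicle to 2219.7 ± 59.3 RPKM (SD, n = 3), a log2 change of 2.85 ± 0.076 (SE). KLK2 (chromosome 19, 51376689 to 51383823), a neighbouring kallikrein, rose by log2 4.0 ± 0.090 and the membrane protease TMPRSS2 (chromosome 21, 42836478 to 42880085) by 3.86 ± 0.085. FKBP5 (chromosome 6, 35541362 to 35688325), a co-chaperone of steroid receptors, rose by 4.41 ± 0.047. For these genes the limma adjusted p was at most 8.42e-10.

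The largest rise was that of STEAP4 (chromosome 7, 87905744 to 87936209), a metalloreductase, from 0.154 ± 0.0373 to 45 ± 2.01 RPKM, log2 6.12 ± 0.10. It was followed by NPPC, the precursor of C-type natriuretic peptide, at 5.36 ± 0.10, and HPGD, which inactivates prostaglandins, at 4.87 ± 0.15. The kinase SGK1 rose by 4.28 ± 0.15, the androgen-conjugating enzyme UGT2B28 by 3.91 ± 0.10, CSGALNACT1, which starts chondroitin sulfate chains, by 3.85 ± 0.11 and ERRFI1, an inhibitor of the EGF receptor, by 3.84 ± 0.051. The acute-phase gene ORM1 rose by 4.4 ± 0.16, and its near-identical neighbour ORM2 was listed at 0 in each vehicle library and at 7.16 ± 0.356 RPKM with R1881. Reads of this pair, and of the UGT2B family, may have been split between copies, so their single values are uncertain. The largest fall was that of LRRN1 (chromosome 3, 3841121 to 3889387), a leucine-rich repeat membrane protein, from 118 ± 3.1 to 7.86 ± 0.123 RPKM, log2 -3.82 ± 0.047. It was followed by FAM198B (-3.58 ± 0.091), CAMK2N1, an inhibitor of the kinase CaMKII (-3.13 ± 0.060), the chemokine receptor CXCR7 (-3.07 ± 0.067) and sucrase-isomaltase, SI (-3.04 ± 0.10). Other falls were those of DDC, which makes dopamine and serotonin (-3.03 ± 0.052), the kappa opioid receptor OPRK1 (-2.77 ± 0.092), butyrylcholinesterase BCHE (-2.69 ± 0.060) and GRB10, an adaptor that restrains insulin receptor signalling (-2.58 ± 0.054). PKIB, a protein kinase A inhibitor (-2.54 ± 0.10), the Golgi mannosidase MANEA (-2.5 ± 0.090) and the uncharacterised LOC647859 (-3.04 ± 0.25) were also among the largest falls. Among these genes the limma adjusted p was at most 5.25e-06.

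**Figure D1:**
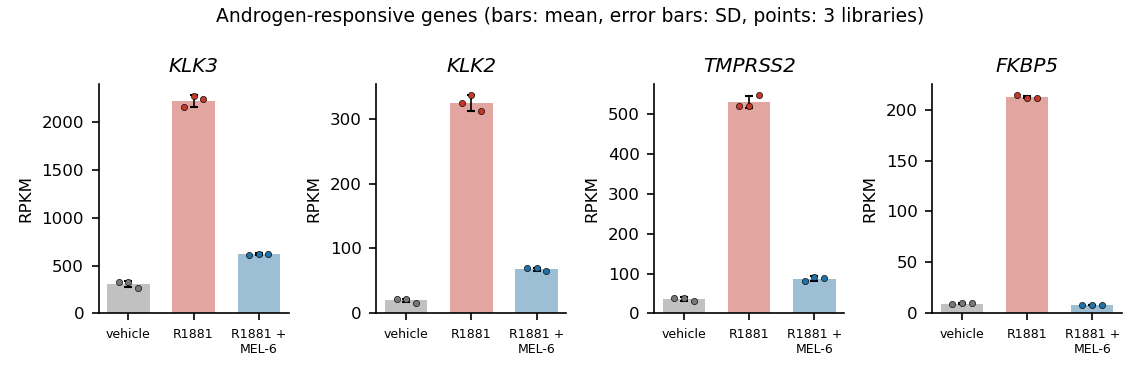
Expression in RPKM of the androgen markers KLK3, KLK2, TMPRSS2 and FKBP5 in the vehicle, R1881 and R1881 with MEL-6 groups, with points for single libraries, bars for the mean and error bars for the SD (n = 3). KLK3 stood at 308, 2219.7 and 619 RPKM in these groups, and FKBP5 at 9.53, 212 and 7.99 RPKM.

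Secretory trafficking genes rose in 23 of 24 cases and fell in 0 (median log2 change 0.62, camera adjusted p = 1.07e-18). Among them were ST6GALNAC1, which sialylates mucin-type glycans (2.78 ± 0.17), UAP1, which makes UDP-N-acetylglucosamine (1.88 ± 0.059), and the COPII coat gene SEC24D (1.49 ± 0.061). ER chaperone genes rose in 19 of 20 cases and fell in 0 (median 0.64, adjusted p = 1.20e-14). DNAJB9 was at 1.57 ± 0.089 and MANF at 0.87 ± 0.075. Cholesterol genes rose in 18 of 24 cases and fell in 2 (median 0.33, adjusted p = 6.38e-09). Squalene synthase FDFT1 was at 0.93 ± 0.058 and the sterol carrier STARD4 at 0.66 ± 0.094, while HSD17B7 and TM7SF2 fell. In the fatty acid list 10 of 20 rose and 3 fell (median 0.21, adjusted p = 1.83e-04; adjusted p = 0.0845 with an estimated correlation). The fatty acid ligase ACSL3 was at 3.1 ± 0.072, the elongase ELOVL7 at 2.92 ± 0.10 and fatty acid synthase FASN at 1.49 ± 0.16. Genes of the polyamine list, which also held the fatty acid racemase AMACR, rose in 6 of 11 cases and fell in 0 (median 0.52, adjusted p = 8.41e-05). Without AMACR 5 of 10 rose (median 0.29, adjusted p = 0.000632). In the lead were spermine synthase SMS (2.13 ± 0.050), the acetyltransferase SAT1 (2.04 ± 0.078) and ornithine decarboxylase ODC1 (1.45 ± 0.044). The list was planned as polyamine synthesis but also held SAT1, PAOX and SMOX, which act in polyamine breakdown. SAT1 and PAOX (0.58) were among the rises, so the list cannot be read as synthesis alone in any comparison. Of 13 glucocorticoid-responsive genes, 9 rose and 2, TSC22D3 and MT2A, fell (median 1.38, adjusted p = 1.53e-07).

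Cell cycle and stress lists moved down with R1881 on the preset correlation. DNA replication genes fell in 28 of 30 cases and rose in 0 (median -0.58, adjusted p = 6.38e-09; adjusted p = 0.0913 with an estimated correlation). Examples were the helicase subunits MCM3 (-0.88 ± 0.073), MCM2 (-0.83 ± 0.12) and MCM4 (-0.80 ± 0.056) and cyclin CCNE2 (-0.85 ± 0.088). Mitosis genes fell in 18 of 26 cases and rose in 0 (median -0.24, adjusted p = 0.00327; adjusted p = 0.142 with an estimated correlation). Among them were the checkpoint kinase BUB1B (-0.55 ± 0.055) and the kinetochore gene NDC80 (-0.42 ± 0.073). Of 20 ATF4 and amino acid stress genes, 14 fell and 1, VLDLR, rose (median -0.46, adjusted p = 0.00136; adjusted p = 0.181 with an estimated correlation). These included the amino acid transporter SLC7A5 (-1.38 ± 0.10), the serine synthesis gene PSAT1 (-1.11 ± 0.048) and CHAC1, which degrades glutathione (-1.07 ± 0.071). Of 20 p53 targets, 13 fell and 3 rose (median -0.39, adjusted p = 0.0128; adjusted p = 0.0845 with an estimated correlation). TP53INP1 (-1.58 ± 0.067) and the sestrin SESN1 (-1.24 ± 0.067) were among those that fell, while the death receptor TNFRSF10B (1.12 ± 0.051), the secreted stress factor GDF15 (1.1 ± 0.10) and PLK2 rose. NRF2 targets were not called as a list (4 of 17 higher, 5 lower, adjusted p = 0.396). This list had a median of -0.029 and a mean of 0.040, opposite in sign, and a test that pointed up. Nor were the 5 tested aryl hydrocarbon receptor targets (1 higher, 1 lower, adjusted p = 0.386, median -0.048 and mean 0.13, with a test that pointed up).

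Markers of the epithelial cell type and of other cells moved as follows. Luminal markers rose in 9 of 14 cases and fell in 4 (median 0.90, adjusted p = 6.98e-05; adjusted p = 0.0935 with an estimated correlation). The keratins KRT8 (2.49 ± 0.10) and KRT18 (1.9 ± 0.063) and the transcription factor SPDEF (2.42 ± 0.094) rose, and HOXB13, CDH1 and GATA2 were among those that fell. Of the basal markers, 2 of 10 reached the tested level and 1, the integrin ITGA6, fell (-0.48 ± 0.091). In the neuroendocrine list 1 of 4 was higher and 2 lower (adjusted p = 0.90, median -0.11, with a test that pointed up). In the fibroblast list 5 of 12 reached the tested level, of which 3 were lower and 0 higher (adjusted p = 0.243). The 1 tested leukocyte marker, CD68, was not called (log2 change 0.087). Replication-dependent histones rose in 4 of 12 cases and fell in 0 (median 0.28, adjusted p = 0.00136; adjusted p = 0.112 with an estimated correlation). The lead was taken by HIST1H1E (1.93 ± 0.21). The histone list was planned as a check of RNA quality, since these transcripts lack a poly(A) tail and polyadenylated RNA was sequenced. Its values, here and in the other comparisons, therefore cannot be read as changes in histone expression.

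In all, 1930 genes were higher and 4155 lower with R1881 out of 13295 tested (limma adjusted p under 0.05), of which 340 and 268 changed at least 2-fold. The groups of 57.9% of the genes did not overlap, against 10% by chance. The median gene shifted by log2 -0.12, and with median-of-ratios scaling, which brought this to -0.02, 49.4% of calls were lower in place of 68.3%, while with upper-quartile scaling 65.6% were lower and the median was -0.104, so small changes near -0.12 depend on the scaling. Adjusted over the list alone, the counts were the same except for NRF2 targets (4 higher, 6 lower), p53 targets (3 and 14), luminal markers (9 and 5) and oxidative phosphorylation (0 and 1).

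The second comparison, R1881 with MEL-6 against R1881, asked what MEL-6 did to cells under androgen, and is the comparison on which the study ran its gene set analysis. KLK3 fell from 2219.7 ± 59.3 to 619 ± 7.46 RPKM (SD, n = 3), log2 -1.84 ± 0.076 (SE). So did KLK2 (log2 -2.24 ± 0.090), TMPRSS2 (-2.6 ± 0.085) and FKBP5 (-4.65 ± 0.047), the last from 212 ± 1.35 to 7.99 ± 0.212 RPKM, with limma adjusted p of at most 2.75e-08. The stress transcription factor DDIT3, also known as CHOP (chromosome 12, 57910434 to 57914300), rose from 14.6 ± 0.653 to 105 ± 4.03 RPKM, log2 2.81 ± 0.054 (adjusted p = 1.63e-10).

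The largest falls after STEAP4 (-6.07 ± 0.10) and FKBP5 were those of ORM1 (-4.47 ± 0.16), SGK1 (-4.37 ± 0.15), the condensin subunit NCAPD3 (-4.27 ± 0.060), NPPC (-3.98 ± 0.10), UGT2B28 (-3.98 ± 0.10), UGT2B11 (-3.78 ± 0.18), HPGD (-3.67 ± 0.15), ORM2 (-3.64 ± 0.15), the transcription factor MAF (-3.48 ± 0.15) and NDRG1 (-3.41 ± 0.061). These 12 genes had all risen with R1881. Of the largest rises, OPRK1 (2.9 ± 0.092), FAM198B (2.74 ± 0.091), LRRN1 (2.73 ± 0.047), CXCR7 (2.63 ± 0.067) and LOC100505633 (2.78 ± 0.17) had fallen with R1881. DIO3 (chromosome 14, 102027688 to 102029789), which inactivates thyroid hormone, rose from 0.303 ± 0.137 to 17.2 ± 1.31 RPKM, log2 4.47 ± 0.14, and had not been called with R1881. The nitric oxide synthase NOS3 (2.95 ± 0.11), the glycoprotein GPNMB (2.92 ± 0.16) and FGF13 (2.74 ± 0.13) also rose, and had been called lower with R1881 (log2 -0.40 ± 0.11, -0.48 ± 0.16 and -0.84 ± 0.13). The R1881 call of NOS3 was lost without R1881 replicate 2 (adjusted p = 0.053). That of GPNMB was lost without vehicle replicate 1 or 3, without any one of R1881 replicates 1, 2 and 3, with no filter and with median-of-ratios scaling (adjusted p up to 0.0972). MIR631 (3.05 ± 0.83, adjusted p = 0.0104) is a short microRNA entry inside the span of NEIL1, so its value is uncertain. Apart from MIR631, these genes had a limma adjusted p of at most 4.78e-07.

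**Figure D2:**
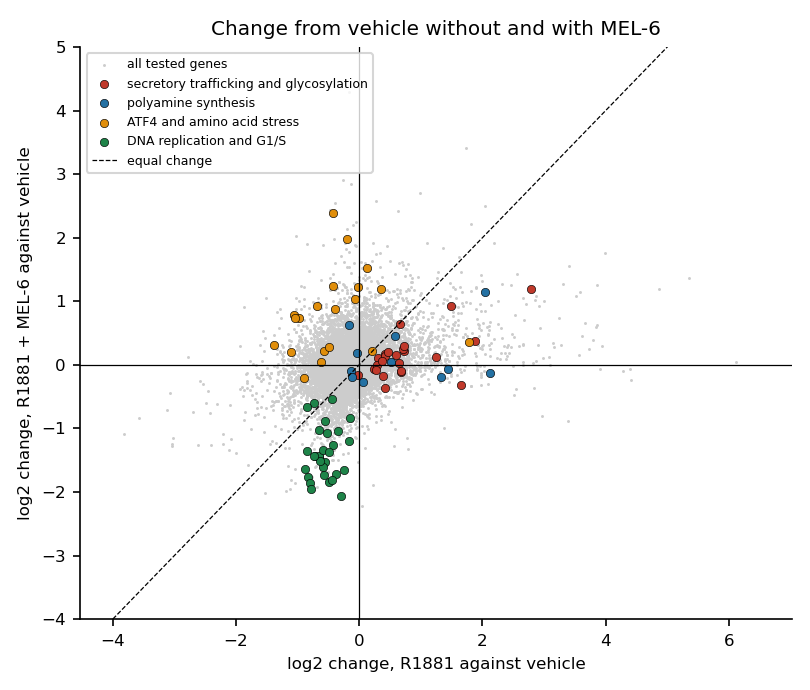
Log2 change with R1881 against vehicle (horizontal) and with R1881 and MEL-6 against vehicle (vertical) for each tested gene, with the genes of the secretory trafficking, polyamine, ATF4 and DNA replication lists in colour and a dashed line of equal change. Secretory trafficking genes had a median of 0.62 on the horizontal axis and 0.11 on the vertical axis.

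Secretory trafficking genes fell in 22 of 24 cases and rose in 0 (median -0.46, camera adjusted p = 2.05e-12). The lead was taken by their regulator CREB3L4 (-1.97 ± 0.067). Cholesterol genes fell in 20 of 24 cases and rose in 1, TM7SF2 (median -0.58, adjusted p = 2.82e-09). STARD4 was at -1.06 ± 0.094 and FDFT1 at -1.01 ± 0.058. In the fatty acid list 12 of 20 fell and 2, ACACB and ME1, rose (median -0.40, adjusted p = 1.51e-04; adjusted p = 0.0845 with an estimated correlation). These included ACSL3 (-3.1 ± 0.072) and the desaturase FADS2 (-1.41 ± 0.10). ER chaperones fell in 14 of 20 cases (median -0.46, adjusted p = 1.94e-04), whereas HERPUD1, XBP1, SEL1L and ATF6 rose. The rise of HERPUD1 was not called with median-of-ratios scaling (adjusted p = 0.149) or without R1881 replicate 2. Genes of the polyamine list fell in 6 of 11 cases and rose in 2 (median -0.34, adjusted p = 0.00198), and without AMACR 5 of 10 fell (median -0.24, adjusted p = 0.0107). SMS was at -2.25 ± 0.050 and ODC1 at -1.52 ± 0.044. Of 13 glucocorticoid-responsive genes, 10 fell and 3 rose (median -0.62, adjusted p = 4.54e-04). The rises were TSC22D3 and the metallothioneins MT2A (1.86 ± 0.11) and MT1X. Luminal markers fell in 8 of 14 cases and rose in 2, CDH1 and GATA2 (median -1.0, adjusted p = 2.91e-04; adjusted p = 0.112 with an estimated correlation). KRT8 was at -2.5 ± 0.10 and SPDEF at -2.11 ± 0.094.

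ATF4 and amino acid stress genes rose in 18 of 20 cases and fell in 1, VLDLR (median 1.29, adjusted p = 1.83e-10). DDIT3, CHAC1 (1.85 ± 0.071), the pseudokinase TRIB3 (2.18 ± 0.062) and the secreted glycoprotein STC2 (1.79 ± 0.056) rose most. DNA replication genes fell in 27 of 30 cases and rose in 0 (median -0.82, adjusted p = 3.66e-15). Among them were the ribonucleotide reductase subunit RRM2 (-1.77 ± 0.064), the flap endonuclease FEN1 (-1.41 ± 0.089) and the origin licensing gene CDC6 (-1.34 ± 0.063). Mitosis genes fell in 22 of 26 cases and rose in 0 (median -0.48, adjusted p = 1.83e-10). These included CDK1 (-0.96 ± 0.074), NDC80 (-0.91 ± 0.073) and cyclin CCNA2 (-0.87 ± 0.049). The p53 targets rose in 17 of 20 cases and fell in 2, TNFRSF10B and PLK2 (median 0.78, adjusted p = 6.59e-05). TP53INP1 was at 1.64 ± 0.067, BBC3, which encodes the cell death protein PUMA, at 1.32 ± 0.11 and the cell cycle inhibitor CDKN1A at 1.22 ± 0.057. NRF2 targets rose in 11 of 17 cases and fell in 2, PRDX1 and GSR (median 0.52, adjusted p = 0.00856; adjusted p = 0.171 with an estimated correlation). In the lead were ferritin heavy chain FTH1 (1.86 ± 0.085), heme oxygenase HMOX1 (1.72 ± 0.069) and the cystine transporter SLC7A11 (1.66 ± 0.056). The aryl hydrocarbon receptor list was not called (adjusted p = 0.517), although 2 of its 5 tested members, CYP1A1 (2.3 ± 0.14) and CYP1A2 (1.71 ± 0.19), were called higher and TIPARP (-1.34 ± 0.078) lower.

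Among markers of other cells, fibroblast genes rose in 4 of 5 cases and fell in 0 (median 1.5, adjusted p = 0.00713; adjusted p = 0.0935 with an estimated correlation). The intermediate filament gene VIM reached 2.06 ± 0.46 RPKM and fibronectin FN1 15.1 ± 0.876 RPKM. Of the 12 genes on this list COL1A2, COL3A1, COL6A3, DCN, LUM, THY1 and PDGFRB lay under the tested level. The rises therefore cannot be read as a fibroblast programme. In the neuroendocrine list 3 of 4 were higher and 0 lower (median 0.49, adjusted p = 0.14). Of 2 basal genes 1, ITGA6, rose (0.80 ± 0.091). CD68, the leukocyte marker, was not called (log2 change 0.18). Histones were split, 3 higher and 3 lower of 12 (adjusted p = 0.276).

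Over all genes, 4175 were higher and 2737 lower with MEL-6 than with R1881 alone, 477 and 315 of them at least 2-fold, and the groups of 59.8% of genes did not overlap (10% by chance). With median-of-ratios scaling 51.5% of calls were lower, in place of 39.6%, and the median gene moved from log2 0.075 to -0.0018, while with upper-quartile scaling 35.4% were lower and the median was 0.103. Of the 1930 genes higher with R1881, 1362 (70.6%) were lower with MEL-6, and of the 4155 lower ones 2526 (60.8%) were higher (1682 of 2635 with median-of-ratios and 2538 of 3855 with upper-quartile scaling), while 438 (7.20%) of the called genes moved further the same way. Simulated unchanged groups that shared the R1881 libraries gave a median of 0 in each case, a value that leaves out all real effects. Independent lists of these sizes would overlap by 397, 1305 and 1461 genes, so the opposite changes lay above that and the changes the same way below. Across genes the log2 changes of the 2 comparisons correlated at r = -0.72 (simulated -0.50), with a covariance of -0.196 (simulated -0.0118). The 3 R1881 libraries were not divided between the comparisons, so part of the excess of opposite changes may come from sharing them. Adjusted over the list alone, the counts were the same except for DNA replication (1 higher, 27 lower), ER chaperones (4 and 15), secretory trafficking (0 and 23), hypoxia (6 and 5) and ribosomal proteins (23 and 0).

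The third comparison, R1881 with MEL-6 against vehicle, measured what was left of the androgen response and what MEL-6 changed beyond it. KLK3 was still above vehicle, at 619 ± 7.46 against 308 ± 32.9 RPKM (SD, n = 3), log2 1.01 ± 0.076 (SE). So were KLK2 (1.76 ± 0.090) and TMPRSS2 (1.26 ± 0.085), with limma adjusted p of at most 4.98e-06. FKBP5 was below vehicle, at 7.99 ± 0.212 against 9.53 ± 0.315 RPKM, log2 -0.24 ± 0.047 (adjusted p = 0.00285), and STEAP4 was not called (0.052 ± 0.10, adjusted p = 0.711). DDIT3, HMOX1 and DIO3 stood above both other groups and replication genes such as RRM2 and MCM4 below both.

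The genes raised furthest above both other groups were DIO3 (log2 4.3 ± 0.14 against vehicle), NOS3 (2.55 ± 0.11), GPNMB (2.44 ± 0.16), DDIT3 (2.39 ± 0.054), the cytochrome CYP1A1 (2.25 ± 0.14), the extracellular matrix protein RELN (2.14 ± 0.094), TRIB3 (1.98 ± 0.062) and FGF13 (1.9 ± 0.13). HMOX1 (chromosome 22, 35777060 to 35790207) rose in steps, from 18.2 ± 1.24 RPKM in vehicle to 36.5 ± 2.04 with R1881 and 121 ± 8.1 with MEL-6. So did the angiogenesis factor ANGPT2 (log2 3.41 ± 0.14 against vehicle), the stress-induced FAM129A (2.42 ± 0.088) and GDF15 (1.92 ± 0.10). GTPBP2 was 1.92 ± 0.074 above vehicle. RRM2 (chromosome 2, 10262695 to 10271546) fell from 43.9 ± 1.37 RPKM in vehicle and 35.7 ± 1.58 with R1881 to 10.1 ± 0.795 with MEL-6, log2 -2.07 ± 0.064 against vehicle. MCM4 (chromosome 8, 48873494 to 48890068) was at -1.86 ± 0.056, MCM10 at -1.95 ± 0.11, MCM2 at -1.77 ± 0.12 and the ubiquitin ligase adaptor DTL at -1.92 ± 0.077. FAM111B was at -1.89 ± 0.055, the replication genes GINS2 at -1.84 ± 0.076 and CDC45, listed as CDC45L, at -1.81 ± 0.064, the transcription factor ZNF367 at -1.77 ± 0.074, the exonuclease EXO1 at -1.76 ± 0.10 and the cohesin acetyltransferase ESCO2 at -1.75 ± 0.089. For these rises and falls the limma adjusted p was at most 3.02e-06. PCNAAS (-1.86 ± 0.24) is antisense to PCNA, itself a replication gene, and without strand their reads cannot be told apart.

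**Figure D3:**
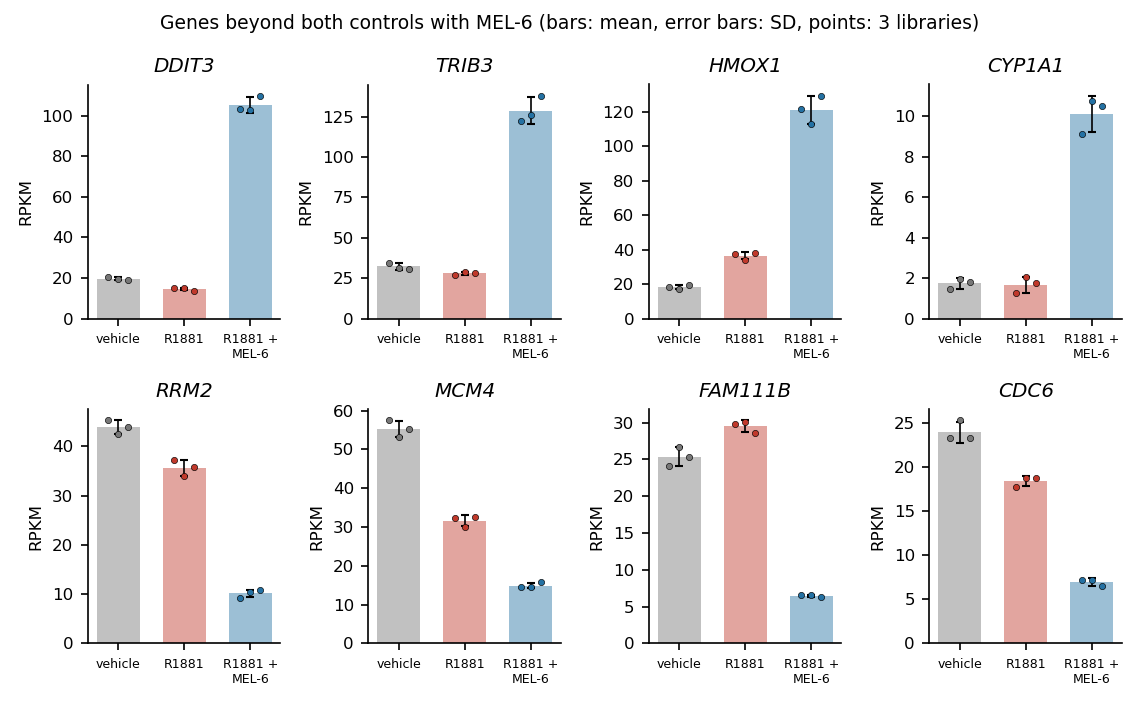
Expression in RPKM of DDIT3, TRIB3, HMOX1, CYP1A1, RRM2, MCM4, FAM111B and CDC6 in the 3 groups, with points for single libraries, bars for the mean and error bars for the SD (n = 3). DDIT3 stood at 19.7, 14.6 and 105 RPKM in vehicle, R1881 and R1881 with MEL-6, and RRM2 at 43.9, 35.7 and 10.1 RPKM.

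Cholesterol genes were mostly near vehicle, with 9 lower and 1, LSS, higher of 24 (median -0.15, camera adjusted p = 0.0431; adjusted p = 0.306 with an estimated correlation). This call was lost without MEL-6 replicate 1 (adjusted p = 0.104) and with median-of-ratios scaling (0.0501). Fatty acid genes (3 higher and 5 lower of 20, adjusted p = 0.517) and luminal markers (3 and 2 of 14, adjusted p = 0.249) were not called. Secretory genes were higher in 9 and lower in 3 of 24 cases (adjusted p = 0.0688). That list was not called, but passed without vehicle replicate 2 (0.0256) and with median-of-ratios scaling (0.0474). ER chaperones rose in 10 of 20 cases and fell in 1, CALR (median 0.19, adjusted p = 1.44e-05). In the lead were DNAJB9 (1.05 ± 0.089) and HERPUD1 (0.97 ± 0.056). Glucocorticoid-responsive genes rose in 9 of 13 cases and fell in 2, FKBP5 and KLF9 (median 0.60, adjusted p = 2.91e-04). MT2A was at 1.43 ± 0.11 and ZBTB16 at 0.96 ± 0.094. In the polyamine list 4 of 11 were higher and 2 lower (adjusted p = 0.574), and without AMACR 4 of 10 were higher and 1 lower (adjusted p = 0.404). The full list had a median of -0.068 and a mean of 0.14, opposite in sign, and a test that pointed up.

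DNA replication genes fell in 30 of 30 cases (median -1.44, adjusted p = 3.60e-27) and mitosis genes in 25 of 26 (median -0.71, adjusted p = 4.52e-16). NDC80 was at -1.34 ± 0.073 and CDK1 at -1.17 ± 0.074. ATF4 and amino acid stress genes rose in 17 of 20 cases and fell in 0 (median 0.76, adjusted p = 4.16e-12). NRF2 targets rose in 11 of 17 and fell in 2, TXN and PRDX1 (median 0.41, adjusted p = 1.92e-06). FTH1 was at 1.62 ± 0.085 and SLC7A11 at 1.24 ± 0.056. The p53 targets rose in 7 of 20 cases and fell in 1, SESN1 (median 0.14, adjusted p = 0.0131; adjusted p = 0.0845 with an estimated correlation). These included BBC3 (1.12 ± 0.11) and CDKN1A (0.92 ± 0.057). Aryl hydrocarbon receptor targets rose in 3 of 5 cases (median 0.27, adjusted p = 0.0199; adjusted p = 0.0935 with an estimated correlation). Fibroblast markers were higher in 4 and lower in 1, FN1, of 5 cases (median 0.48, adjusted p = 0.0449; adjusted p = 0.181 with an estimated correlation). The call of FN1 ended without vehicle replicate 1 (adjusted p = 0.0757), without MEL-6 replicate 1 and in the fit on the compared groups alone. ACTA2, an actin of smooth muscle, was at 6.51 ± 0.493 against 2.34 ± 0.267 RPKM. The list's call ended with median-of-ratios scaling (adjusted p = 0.0551) and without vehicle replicate 3 (0.0671), MEL-6 replicate 1 (0.0658) or MEL-6 replicate 3 (0.0529). Neuroendocrine markers were higher in 2 of 4 cases and lower in 0 (adjusted p = 0.0651). Of 2 basal genes 1, ITGA6, was higher (0.33 ± 0.091, a call lost without vehicle replicate 1 at adjusted p = 0.0531), and CD68 was not called (log2 change 0.26). Histones were higher in 5 and lower in 1 of 12 cases (median 0.29, adjusted p = 0.0431; adjusted p = 0.277 with an estimated correlation). That call ended with median-of-ratios scaling (adjusted p = 0.0523) and without vehicle replicate 2 (0.145).

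**Figure D4:**
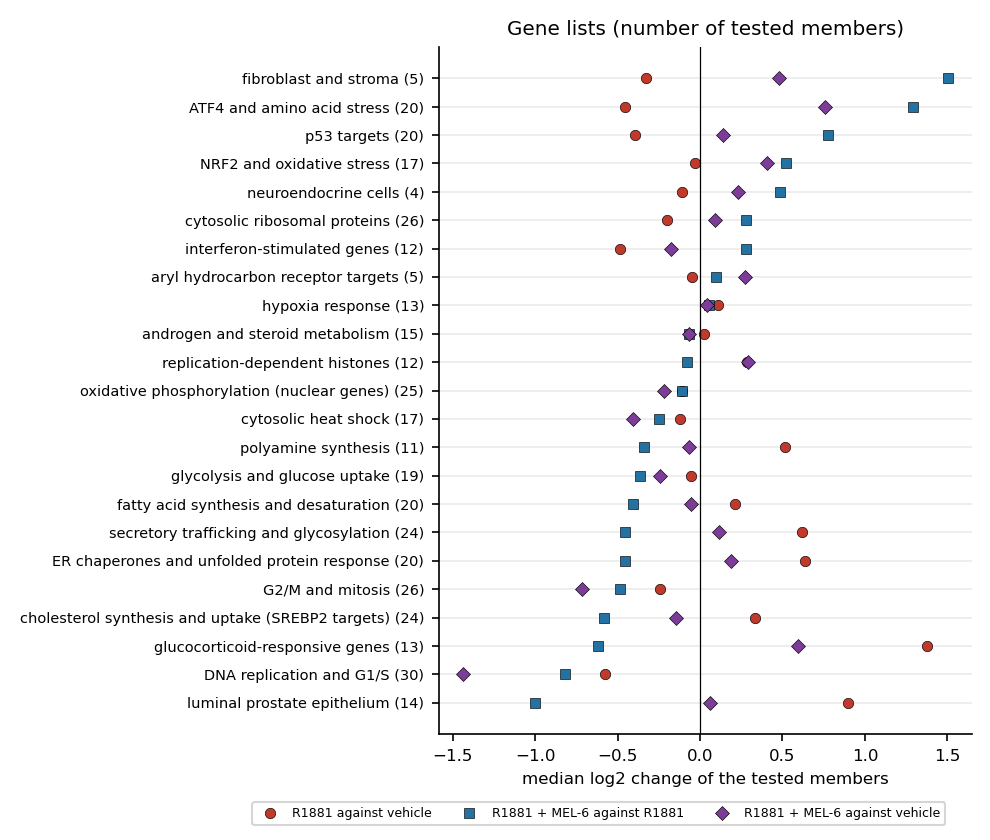
Median log2 change of the tested members of 23 gene lists in the 3 comparisons, with the number of tested members beside each name. Secretory trafficking genes lay at 0.62, -0.46 and 0.11 for R1881 against vehicle, MEL-6 against R1881 and MEL-6 against vehicle, and DNA replication genes at -0.58, -0.82 and -1.44.

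Over all genes, 2290 were higher and 2761 lower with R1881 and MEL-6 than with vehicle, 178 and 138 of them at least 2-fold, and the groups of 46.5% did not overlap (10% by chance). Of these calls 54.7% were lower, against 48.8% with median-of-ratios and 44.1% with upper-quartile scaling. Among genes higher with R1881, a median of 21% of the log2 response was left with MEL-6 (interquartile range -10.2 to 59.4%, 1930 genes), and among those raised at least 4-fold 12.8% (95 genes, of which 93 were lower with MEL-6). For genes lower with R1881 the median was 25.4% (-22.0 to 79.4%, 4155 genes) and for those lowered at least 4-fold 28.6% (21 genes, each higher with MEL-6). These genes were chosen on the response itself and the vehicle libraries enter both changes. With upper-quartile scaling the lower genes kept 15.8%. The 2 changes against vehicle correlated at r = 0.31 across genes (simulated 0.50), with a covariance of 0.0604 (simulated 0.0117). MEL-6 moved 1499 genes above both other groups and 1330 below both, where simulated unchanged groups, without real effects, gave a median of 0 and independent lists would give 719 and 568, and part of the excess may come from the shared MEL-6 libraries. Adjusted over the list alone, the counts were the same except for fatty acid synthesis (4 higher, 6 lower), ATF4 (17 and 1), ER chaperones (11 and 1), heat shock (1 and 12), NRF2 targets (12 and 2), polyamine synthesis (4 and 4), secretory trafficking (10 and 4), ribosomal proteins (0 and 0) and oxidative phosphorylation (0 and 16).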

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

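Pseudocounts of 0.1 and 1, the test without features of 500 bp or less and the polyamine list without AMACR were chosen after the data were seen, and the other alternatives were planned. The planned count tests were not run, since the values are not counts. The planned scaling by trimmed means was not run either, although median-of-ratios and upper-quartile scaling were run on RPKM. No called result changed sign under any alternative that was run. Of 228 recomputed counts and shares 215 stayed within 1.5 times the reported count or within the spread of the reported share, and 13 moved. Of 831 list tests 784 kept their direction and side of the threshold, 3 came to pass it, and 44 no longer passed it, of which 26 were with the estimated correlation, 14 with a library left out and 4 with median-of-ratios scaling. Of 8286 tests of named genes 8036 kept both and 250 no longer passed, 162 of these with a library left out, 25 with median-of-ratios scaling and 24 without a filter. Median-of-ratios scaling gave 2635 genes lower with R1881 in place of 4155 and 1682 of these genes higher with MEL-6 in place of 2526. By its construction it takes out the shift of the median gene, which went from log2 -0.12 to -0.02. Of the calls reported, it kept 75%, 88.7% and 93.4% in the same direction for R1881 against vehicle, MEL-6 against R1881 and MEL-6 against vehicle. The share of the R1881 response left in genes that R1881 raised, 21%, was 29.1% with upper-quartile scaling and 25.1% with limma-voom, and with a library left out it lay between 19.7% (without MEL-6 replicate 3) and 24.1% (without vehicle replicate 1). In genes that R1881 lowered the share, 25.4%, was 19.6% with median-of-ratios and 15.8% with upper-quartile scaling, 27.5% without a filter, 22% with limma-voom and 23.6% with a pseudocount of 0.1. With a library left out it lay between 24.0% (without R1881 replicate 3) and 28.6% (without vehicle replicate 3). For these shares the cause was not tested.

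Replicate numbers did not pair the libraries. Deviations from the group means correlated at r = -0.197 to 0.198 across genes between libraries of the same number, and 1 of 9 libraries correlated best with its own number in both other groups. With the numbers as a block, 1817 genes were higher and 3831 lower with R1881, 3983 and 2574 with MEL-6 against R1881, and 2028 and 2475 with MEL-6 against vehicle. Depth limits the low genes, since 3 reads in a 2 kb gene made up to 0.227 RPKM in the shallowest library. At this replication 55.2% to 64.2% of simulated changes of log2 0.5 were recovered. Few genes were changed in that simulation, which makes the adjusted threshold stricter than here, where 38.0% to 52.0% of genes were called. These shares are therefore not the recovery in the real comparisons.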

Other observations

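The tests chosen only after their results were seen were the splits of the libraries, the 3 tests of scaling, MEL-6 replicate 1 and the androgen-free state on the stress and replication genes, and the scaling test on the genes lower with R1881.

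Lists that answered no comparison of the report moved as follows. Cytosolic heat shock genes were not called with R1881 (2 higher and 6 lower of 17, camera adjusted p = 0.506). With MEL-6 they were lower in 11 cases and higher in 4 against R1881 (median log2 change -0.25, adjusted p = 0.0135; adjusted p = 0.181 with an estimated correlation) and lower in 11 and higher in 1 against vehicle (median -0.40, adjusted p = 1.07e-04; adjusted p = 0.0702 with an estimated correlation). The chaperone HSPH1 was at -0.62 ± 0.048 against R1881 and CRYAB, in the other direction, at 1.27 ± 0.26. Glycolysis genes were not called with R1881 (6 higher, 5 lower of 19, adjusted p = 0.153, median -0.057, mean 0.21, with a test that pointed up). They fell with MEL-6 in 15 cases and rose in 1, PFKM, against R1881 (median -0.36, adjusted p = 3.73e-05; adjusted p = 0.181 with an estimated correlation). Against vehicle 10 were lower and 2 higher (median -0.24, adjusted p = 0.0162; adjusted p = 0.42 with an estimated correlation). Lactate dehydrogenase LDHA was at -0.94 ± 0.050 against R1881. Hypoxia genes rose with R1881 in 5 and fell in 3 of 13 cases (median 0.11, adjusted p = 0.0176; adjusted p = 0.0845 with an estimated correlation). They were not called against R1881 (adjusted p = 0.521, median 0.053, mean -0.30, with a test that pointed down) or against vehicle (adjusted p = 0.418).

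Of 12 interferon-stimulated genes 6 fell and 0 rose with R1881, and 6 rose and 1, OAS3, fell with MEL-6 against R1881, with no call of the list in the 3 comparisons (adjusted p = 0.103, 0.372 and 0.417). Steroid metabolism was not called either (adjusted p = 0.0642, 0.0983 and 0.307), except without vehicle replicate 1 for R1881 against vehicle (0.0358), and UGT2B17 was at -2.12 ± 0.081 with R1881. Ribosomal protein genes fell in 11 of 26 cases with R1881 and rose in 0 (median -0.20, adjusted p = 0.0331; adjusted p = 0.573 with an estimated correlation). That call ended with median-of-ratios scaling (0.0846) and without vehicle replicate 1 (0.0968), R1881 replicate 1 (0.103) or R1881 replicate 2 (0.0543). They rose in 18 cases with MEL-6 against R1881 (median 0.28, adjusted p = 4.54e-04; adjusted p = 0.42 with an estimated correlation). Against vehicle 2 were higher and 0 lower (median 0.092, adjusted p = 0.0431; adjusted p = 0.573 with an estimated correlation), a call that ended without vehicle replicate 2 (0.148), vehicle replicate 3 (0.0581) or MEL-6 replicate 3 (0.291). Oxidative phosphorylation genes were not called with R1881 (adjusted p = 0.175). They fell in 7 of 25 cases and rose in 1 against R1881 (median -0.11, adjusted p = 0.039; adjusted p = 0.289 with an estimated correlation), a call that ended without R1881 replicate 3 (0.063), MEL-6 replicate 1 (0.0696) or MEL-6 replicate 2 (0.0517). Against vehicle 15 were lower and 0 higher (median -0.22, adjusted p = 2.26e-04; adjusted p = 0.0945 with an estimated correlation).

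The authors' own columns marked 552 genes between vehicle and R1881, 208 of them higher and 344 lower in vehicle, and 569 between MEL-6 with R1881 and R1881, 254 higher and 315 lower. Of the 542 and 560 of these that were tested here, 539 and 559 were called in the same direction. The pooled SD in the deposited table was 2 times the usual pooled SD in each of the 18725 and 18852 genes compared.

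The 6 libraries of each comparison can be split in 10 ways, so the share of splits with as many calls cannot go below 0.1. The real split gave 6085, 6912 and 5051 calls in the comparisons in the order of the report, and limma called 0 genes in the highest of the other splits in each, so the real one was the 1 split of 10 with as many. At an unadjusted p under 0.05 the real splits gave 7033, 7703 and 6281 genes and the highest of the others 262, 554 and 1376. Each other split put libraries of both groups on each side, so the difference between the groups entered the spread. Few calls could then arise, and these counts cannot decide whether chance gave the real ones.

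With MEL-6, 16 of 20 ATF4 and amino acid stress genes stood above both other groups and 27 of 30 DNA replication genes below both. These 43 genes were picked as already beyond both groups, so staying so was likely in each test. With median-of-ratios and with upper-quartile scaling 100% of them stayed so. The factors of both lay between 0.956 and 1.04, small beside list medians of log2 -0.82 (replication, against R1881) and 0.76 (ATF4, against vehicle). This argues only against scaling of that size. The tables argue against depth, since 97.7% stayed so after every library was thinned to the shallowest. They also argue against MEL-6 replicate 1 alone, since 100% stayed so without it. A return to the androgen-free state would raise the replication genes, of which 28 of 30 were called lower singly with R1881 (median log2 change -0.58; as a list not called with an estimated correlation, adjusted p = 0.0913), but their median against R1881 was -0.82 (SD 0.441 over genes). A candidate explanation is that MEL-6 changes these genes by a route other than the loss of the androgen signal. As there was no group with MEL-6 and no R1881, this stays a hypothesis.

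Of the genes called with R1881, 68.3% were lower. The tables argue against depth, since 66.8% were lower after thinning, against 67.8% of the same 12056 genes at full depth. Scaling stays open, since 65.6% were lower with upper-quartile scaling, and the 49.4% with median-of-ratios scaling, which centres the median gene by its construction, cannot decide. The 317 genes raised at least 2-fold that had an exon length held 1.8% of estimated reads in vehicle, 6.97% with R1881 and 2.41% with MEL-6, which would shift all others by log2 -0.078 where the median gene shifted by -0.12. This lies between the bounds set for and against that cause, so it stays open, and a true fall in many transcripts cannot be told apart from it or from scaling without a measure of total RNA.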
